A study of Mus musculus with 6 samples.

How the data were processed

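RNA of 6 samples, 3 of untransfected Tet-off MEF cells and 3 of HA-Fbxl10 cells, was hybridised to Affymetrix arrays. Per the labels' protocols, 300 ng of total RNA was used per array, RNA integrity was checked on a Bioanalyzer, and targets were labelled with biotin. The deposited table holds log2 expression values per probe set, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, normalises arrays by quantiles and summarises probes on the log2 scale. Its version and settings are not given in the sources used here. The values ran from 1.72 to 13.9 with near-equal quartiles on all arrays, as RMA gives, so they were used without further normalisation. RMA makes the arrays' distributions alike, so a shift common to most genes cannot be seen, and low values are compressed. The table gives no detection calls, scan dates or array batches, so batch was not tested.

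Of 35556 probe sets, 21789 have 1 gene in the platform annotation, 1621 have several and 12146 are unnamed here, controls included. Symbols were updated through the Entrez identifier (21698 probe sets) or an accession (3) to the RefSeq table of assembly GRCm38.p6, and 88 kept the annotation's symbol. The build of the deposited values is not given in the sources used here, so that table served only for names, chromosomes and gene order. Probe sets with several genes or none were left out of gene counts. For the 1001 genes with more than 1 probe set the one with the highest mean over all arrays was used, which left 19936 genes. No filter on dim genes was applied.

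The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over genes, threshold 0.05). Fold changes are HA-Fbxl10 minus control on the log2 scale with moderated standard errors. Replicates carry the same numbers in both groups, which entered the model only in an alternative. A total of 28 gene lists with 724 entries, 677 of them measured, was tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation camera has 4 residual degrees of freedom, and 0 lists passed the adjusted threshold while 3 had an unadjusted p under 0.05. The lists covered chemokines, interferon response, cytokines and acute inflammation, DNA replication, mitosis, p53 targets and CDK inhibitors, glycolysis, TCA cycle and respiratory chain, amino acid metabolism, cholesterol synthesis, matrix proteins, matrix proteases, adhesion, actin and contractile genes, Polycomb members, Hox genes, antioxidant genes, ribosome biogenesis, endoplasmic reticulum stress, growth factors and 8 sets of markers of other cell types or germ cells.

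The samples' groups, the tests, the lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule took Kdm2b, the 6 largest rises and 6 largest falls among genes past the threshold whose groups did not overlap, and from each list the 2 members (3 for chemokines) with the largest change among those past the threshold. Members that ran against their list, and chemokines beyond the rule, were named after their values were seen. The other settings were quantile normalisation of the values, subtraction of array medians, leaving out the dimmest 30% of genes, averaging a gene's probe sets, variance trends with and without robust estimation, array weights, the replicate number as a block, leaving out each array, an adjusted p of 0.01, all probe sets by identifier, and an estimated correlation in camera. Removing chromosome medians, or a running median of 31 neighbouring genes, was added after seeing the data. Both were applied to expressed genes, defined as those above the median of the mean level over all 6 arrays. Other genes kept their values, and each expressed gene counted in its own running median.

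The test was checked on data simulated for HA-Fbxl10 against control over 19936 genes with the real means and spreads and 200 changed genes. The changed genes were all drawn from those above the median level, and noise was drawn independently for each gene. Recovery among dimmer genes and the effect of correlated genes were thus not checked. For these brighter genes the test recovered 76.1% of changes of 0.5, 95.5% of changes of 1 and 100% of changes of 2 on the log2 scale. There were 6 false calls among 187. A simulated shift of -0.4 in 1 list was recovered by camera with 0 other lists called. Random lists, 10000 per set, were matched on mean expression in numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.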

Results

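Gene expression was measured on Affymetrix microarrays in mouse embryonic fibroblasts (MEFs) of a Tet-off line, in which a tetracycline-controlled transactivator drives transgenes. The control group held 3 RNA samples of the untransfected line. The other group held 3 RNA samples of cells of the same line that carried an HA-tagged Fbxl10 cDNA, taken from clones selected for its expression. Fbxl10, now named Kdm2b, encodes a histone demethylase with a JmjC domain and a CpG-binding domain. The RNA samples of each group are described as independent, but nothing says that they came from separate clones or cultures, so the p-values measure only the spread between these samples, which may be technical. The comparison asks which transcripts differed in level between the HA-Fbxl10 cells and the untransfected line. No group with an empty vector was among the samples. Effects of transfection and of clone selection therefore cannot be told apart from those of Fbxl10 for any gene below. Array medians lay between 4.69 and 4.79 on the log2 scale. Pearson correlations over all probes were 0.994 to 0.996 within groups and 0.990 to 0.992 between groups, and each pair of arrays held exactly equal values at 33 to 73 of 35556 probe sets. The number of arrays limits the precision of every value below.

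Kdm2b itself was 5.03-fold higher in HA-Fbxl10 cells. Its log2 level was 7.37 ± 0.08 (SD, n = 3) in control cells and 9.70 ± 0.10 (SD, n = 3) in HA-Fbxl10 cells, a difference of 2.33 ± 0.08 (SE, limma adjusted p = 3.31e-07). The gene has 1 probe set with a single gene name, and whether the transfected cDNA covers all of its probes is not given in the sources used here. Of 19936 genes tested, 4208 passed an adjusted p of 0.05, with 2097 higher and 2111 lower in HA-Fbxl10 cells. That is 21.1% of genes, and among expressed genes the share ran from 24.7% on chromosome 2 to 55.4% on chromosome 3 (chromosomes 1 to 19 and X). The list counts below are to be read against these shares. Changes of at least 2-fold were fewer, 73 genes higher and 118 lower. The 3 arrays of each group did not overlap for 36% of genes, against 10% by chance.

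The largest falls were those of Xist and Sfrp2. Xist, the non-coding RNA that coats the inactive X chromosome in female cells, was 32.2-fold lower, from a log2 level of 8.25 ± 0.25 to 3.24 ± 0.18 (SD, n = 3 each). The lower level lay below the lower quartile of the tested genes (3.69 to 3.78 over the arrays), where these values do not tell signal from background, so the fold is best read as a lower bound. Sfrp2, a secreted Wnt antagonist, was 27.1-fold lower, from 9.40 ± 0.10 to 4.64 ± 0.18. Akip1, the retinoic acid carrier Crabp2, the metallothionein Mt2 and the choline transporter Slc5a7 followed, with log2 fold changes of -3.07, -2.93, -2.66 and -2.52. Besides that of Kdm2b, the largest rises were those of Xlr at 2.39, Slfn4 at 2.34, the tolloid-like protease Tll1 at 2.31, the cartilage collagen Col2a1 at 2.21 and the secreted Wnt modulator Dkk2 at 2.15 on the log2 scale. Their standard errors were 0.08 to 0.16, and every one passed the limma test with an adjusted p of 2.47e-05 or less. Xlr, Slfn4 and Mt2 belong to families with closely related copies, so their probes may not separate the members. Col2a1 was the most variable of these 5 rising genes in control cells (7.16 ± 0.39, SD, n = 3).

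Of 31 chemokine genes measured, 9 fell, 1 rose and 21 did not pass the test. Adjusted over the list alone, 10 fell and 2 rose. Ccl5, an attractant of T cells and monocytes, fell from 9.12 ± 0.14 to 6.63 ± 0.09 (SD, n = 3 each), which is 5.58-fold. Ppbp, which encodes a platelet-derived CXC chemokine, fell from 7.49 ± 0.22 to 5.18 ± 0.06, and the interferon-inducible Cxcl10 fell from 7.06 ± 0.10 to 5.18 ± 0.04. Ccl7 (-1.75), Ccl2 (-1.43), Cx3cl1 (-0.94), Cxcl12 (-0.65), Ccl9 (-0.39) and Cxcl1 (-0.37, all log2 fold changes) also fell, and the 1 gene that rose was Ccl25 (0.38). These last 7 were named after their values were seen. The list's median log2 fold change was -0.07, since most of the other members had small changes, and it was -0.04 without control replicate 2 and -0.05 without HA-Fbxl10 replicate 2. Cxcl1 lost its call without any 1 array (adjusted p of 0.0516 to 0.128) other than control replicate 3, and Ccl25 lost it when probe sets were averaged (0.0654). None of the members named as falling had a mean level over all 6 arrays below the median of all genes (5.36). In HA-Fbxl10 cells alone Ppbp and Cxcl10 (both 5.18) and Ccl9 lay below it. The list was chosen because the study's published work is known to concern chemokine expression, so it is not independent evidence of its direction. The camera set test gave an adjusted p of 0.00792 for the list as a whole, and the adjusted p was 0.317 with an estimated correlation.

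**Figure D1:**
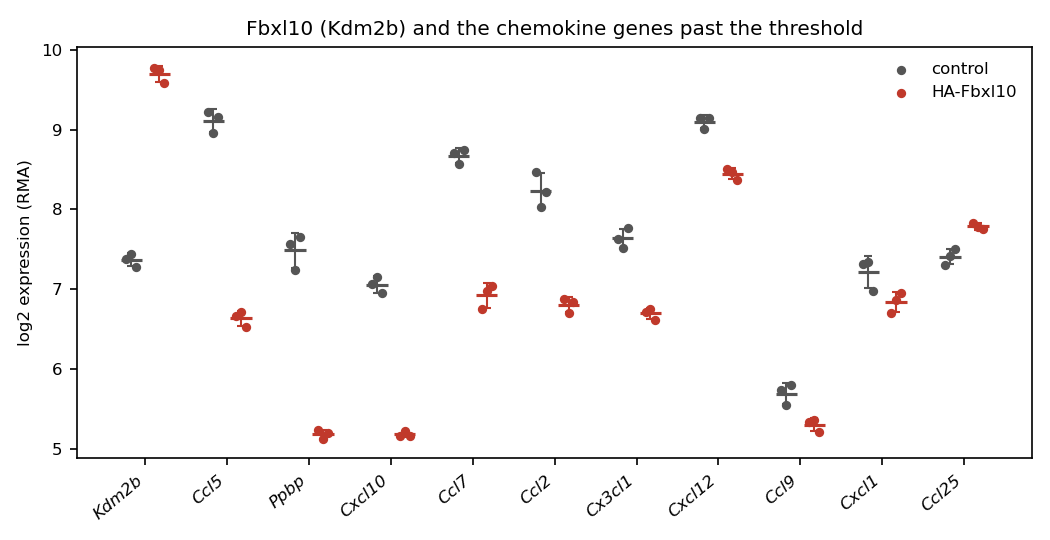
Log2 expression (RMA, vertical axis) of Fbxl10 (Kdm2b) and of the 10 chemokine genes past the threshold (horizontal axis). Points are single arrays, horizontal lines are group means and error bars are SDs (n = 3 each). Kdm2b and Ccl25 were higher in HA-Fbxl10 cells and the other 9 genes were lower.

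Of 26 interferon-response genes measured, 12 fell, 1, Ifit2 (log2 fold change 0.72), rose and 13 did not pass the test. Adjusted over the list alone, 13 fell and 1 rose. Ifit1, an interferon-induced binder of viral RNA, fell by 1.99 ± 0.13 (SE), a lower bound since its HA-Fbxl10 level lay below the lower quartile of genes, and Ifi35 fell by 1.23 ± 0.09 on the log2 scale. The list median was -0.28, and its camera adjusted p was 0.00012, while the adjusted p was 0.317 with an estimated correlation. In the list of cytokines and acute inflammation genes, 8 of 24 fell and 0 rose, with the same 8 falling when adjusted over the list alone. The NF-kappaB subunit gene Nfkb2 fell by 0.74 ± 0.08 (SE) and the receptor gene Tlr2 fell by 0.70 ± 0.10. The camera adjusted p of this list was 0.0428 and its adjusted p was 0.317 with an estimated correlation. This call also ended without control replicate 3 (adjusted p = 0.101) or HA-Fbxl10 replicate 1 (adjusted p = 0.0802), within a range of 0.0316 to 0.317 over its alternatives.

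Of 30 DNA replication and S-phase genes, 15 rose, 1, the primase subunit gene Prim1 (-0.37), fell and 14 did not pass the test. Adjusted over the list alone, 17 rose and 2 fell. Rrm2, the small subunit of ribonucleotide reductase, rose by 0.71 ± 0.07 (SE) and Rfc4, a subunit of the clamp loader, rose by 0.43 ± 0.09 on the log2 scale. The list median was 0.23 with a camera adjusted p of 0.000189, and the adjusted p was 0.683 with an estimated correlation. Mitotic genes went both ways, with 4 of 29 higher and 3 lower (5 and 3 adjusted over the list alone), and their camera adjusted p was 0.881. Ttk, a spindle checkpoint kinase gene, rose by 0.39 ± 0.07 and the kinesin gene Kif20a rose by 0.38 ± 0.07. Among 22 p53 targets and CDK inhibitor genes, 10 fell, 2, Cdkn1b (0.39) and Ei24 (0.34), rose and 10 did not pass the test. Adjusted over the list alone, 10 fell and 3 rose. Perp, a p53-induced membrane protein gene, fell by 1.19 ± 0.08 and Sesn1, a stress-induced sestrin gene, fell by 1.04 ± 0.07. The list median was -0.16 with a camera adjusted p of 0.000344, and the adjusted p was 0.317 with an estimated correlation.

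Of 19 cholesterol synthesis genes measured, 11 rose, 1, Pmvk (-0.37), fell and 7 did not pass the test. Adjusted over the list alone, 13 rose and 2 fell. Idi1, an isomerase of the isoprenoid pathway, rose by 1.20 ± 0.08 (SE), and Insig1, a sterol-regulated gene whose product retains the SREBP activation complex, rose by 0.85 ± 0.07 on the log2 scale. Both probe sets of Idi1 gave a log2 fold change of 1.20. The list median was 0.26 with a camera adjusted p of 7.41e-05, and the adjusted p was 0.317 with an estimated correlation. Of 27 genes of amino acid, serine and one-carbon metabolism, 9 fell and 2, Odc1 (0.32) and Bcat1 (0.26), rose, while 10 fell and 3 rose when adjusted over the list alone. Cth, which makes cysteine from cystathionine, fell by 1.22 ± 0.06 and the cystine transporter gene Slc7a11 fell by 0.89 ± 0.10. Bcat1 lost its call without control replicate 1 or 2 or HA-Fbxl10 replicate 2 or 3 (adjusted p of 0.0511 to 0.0668). The list's camera adjusted p was 0.0228 and its adjusted p was 0.683 with an estimated correlation. It was 0.0623 without HA-Fbxl10 replicate 1, within a range of 0.00428 to 0.683 over its alternatives.

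The glycolytic and mitochondrial lists did not pass the set test. In glycolysis, 3 of 20 genes fell and 1 rose (camera adjusted p = 0.881), and the counts were the same over the list alone. Phosphofructokinase genes went in opposite directions, with Pfkp higher by 0.89 ± 0.07 (SE) and Pfkl lower by 0.69 ± 0.07 on the log2 scale. Of 28 genes of the TCA cycle and respiratory chain, 3 rose and 6 fell, both over all genes and over the list alone (camera adjusted p = 0.954). Idh3a, a subunit of isocitrate dehydrogenase, rose by 0.56 ± 0.07, and Ndufv1, a complex I subunit gene, fell by 0.52 ± 0.07.

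Matrix, adhesion and cytoskeletal genes changed in both directions. Of 29 collagen and matrix genes, 7 rose and 5 fell (9 and 8 adjusted over the list alone, camera adjusted p = 0.881). Postn, a matricellular protein gene, fell by 1.93 ± 0.12 (SE) and Col12a1 rose by 0.90 ± 0.09. Of 25 matrix proteases and inhibitors, 6 rose and 7 fell, with the same counts over the list alone (camera adjusted p = 0.787). The gelatinase gene Mmp9 fell by 1.42 ± 0.09 and Plat, the tissue plasminogen activator gene, fell by 1.04 ± 0.07. Of 28 integrin, Src and focal adhesion genes, 6 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.397). The 2 that fell were the collagen receptor subunit gene Itga11 (-0.81 ± 0.07) and Itgb3 (-0.62 ± 0.12). Of 30 actin and contractile genes, 7 rose and 5 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.848), with Ccn2, a secreted matricellular factor, higher by 0.90 ± 0.06 and the tropomyosin gene Tpm2 lower by 0.60 ± 0.06. Of 35 growth factor and receptor genes, 9 rose and 8 fell (11 and 8 adjusted over the list alone, camera adjusted p = 0.881). Hgf, the ligand of the Met receptor, fell by 1.45 ± 0.07 and the IGF-binding protein gene Igfbp4 fell by 0.97 ± 0.18. The HA-Fbxl10 level of Hgf lay below the lower quartile of genes. Its control level (5.07) lay below the median of all genes (5.36), so the size of its fall is uncertain.

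The chromatin and stress-response lists did not pass the set test either. Of 28 Polycomb complex members, 3 rose and 5 fell, both over all genes and over the list alone (camera adjusted p = 0.881). Besides Kdm2b, the largest change was in Pcgf3, a RING-finger subunit gene, which rose by 0.55 ± 0.07 (SE). Of 37 Hox genes, 5 rose and 2 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.881), with Hoxd13 higher by 0.53 ± 0.08 and Hoxd8 by 0.51 ± 0.12. The list's median was -0.03 although its mean was 0.01 and camera gave its direction as higher. Without single arrays the median ran from -0.0621 to 0.0153, so its sign is not settled. Of 27 antioxidant and glutathione genes, 6 rose and 8 fell (9 and 9 adjusted over the list alone, camera adjusted p = 0.954). The quinone reductase gene Nqo1 fell by 1.56 ± 0.10 and the glutathione transferase gene Gsta4 fell by 0.82 ± 0.06. Of 29 ribosome biogenesis genes, 5 rose and 0 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.831), with Gnl3 higher by 0.49 ± 0.06 and Heatr1 by 0.27 ± 0.07. The call of Heatr1 ended without control replicate 1 or 2 or HA-Fbxl10 replicate 1 or 2 (adjusted p of 0.0789 to 0.0952). Of 24 endoplasmic reticulum stress and ATF4 target genes, 5 rose and 9 fell (6 and 9 adjusted over the list alone, camera adjusted p = 0.831). Vldlr, a lipoprotein receptor gene, fell by 1.78 ± 0.13 and the pseudokinase gene Trib3 fell by 1.04 ± 0.08.

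**Figure D2:**
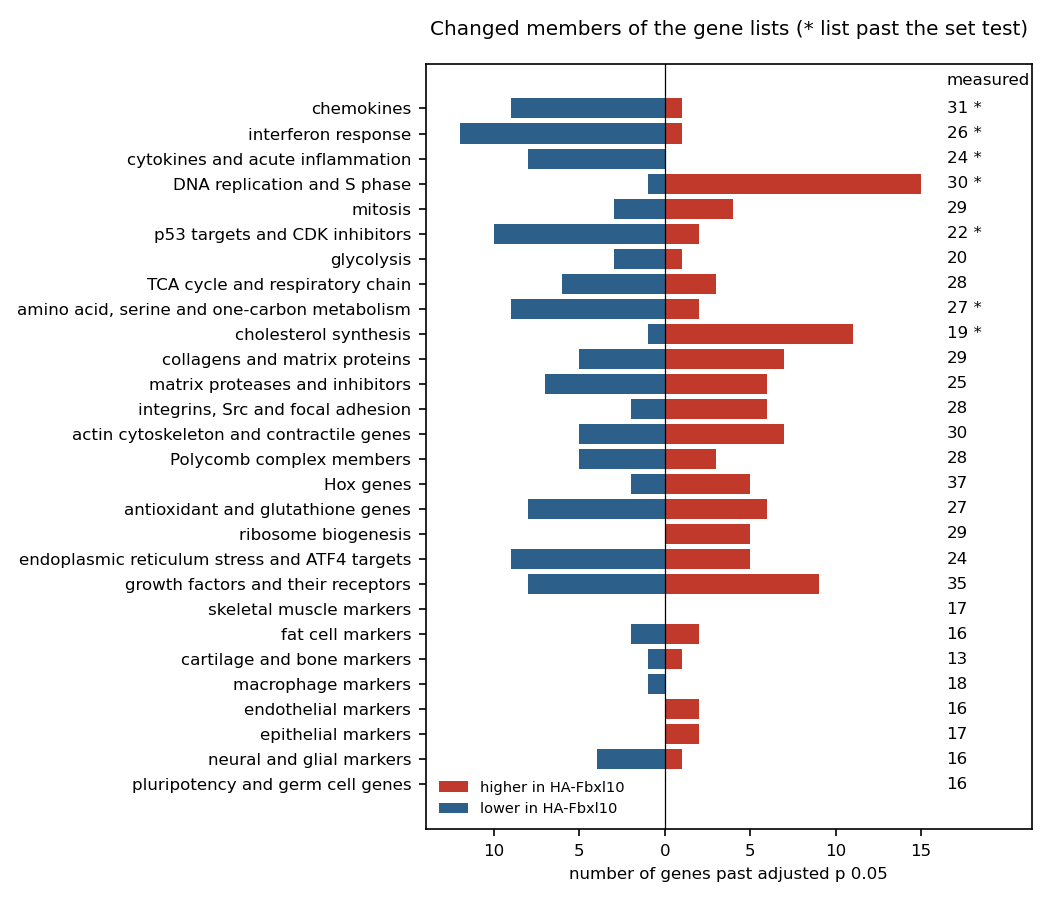
Number of genes past an adjusted p of 0.05 (horizontal axis) in each of the 28 gene lists (vertical axis), higher to the right and lower to the left. The numbers at the right are genes measured, and an asterisk marks the 7 lists past the camera test with its preset correlation. Of the 7, cholesterol synthesis and DNA replication had mostly higher genes and the other 5 mostly lower ones.

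Markers of other cell types mostly did not pass the test, and none of these lists passed camera (adjusted p of 0.315 to 0.954). Among 17 skeletal muscle markers limma called 0, with 0 at an unadjusted p under 0.05, and among 16 pluripotency and germ cell genes it called 0, with 2 at an unadjusted p under 0.05. Of 18 macrophage markers 1 fell, Cd14 (-0.45 ± 0.13, SE), and 0 passed when adjusted over the list alone. Its call ended without replicate 1 or 3 of either group (adjusted p of 0.085 to 0.119). The mean levels of 16 of these 18 markers lay below the median of all genes, and 11 lay above the lower quartile. Of 16 fat cell markers 2 rose and 2 fell, with Lpl higher by 1.04 ± 0.12 and Fabp4 by 0.61 ± 0.07. The control levels of Lpl and of Kdr below lay under the lower quartile of genes. Their HA-Fbxl10 levels (4.49 and 4.20) lay under the median of all genes (5.36), so the size of both rises is uncertain. Of 13 cartilage and bone markers Col2a1 rose, and Sox9 fell by 0.37 ± 0.09, a call that ended without control replicate 2 (adjusted p = 0.0604) or HA-Fbxl10 replicate 2 (0.0588). Of 16 endothelial markers 2 rose, the VEGF receptor genes Flt1 (1.62 ± 0.10) and Kdr (0.51 ± 0.09). Of 17 epithelial markers 2 rose, the keratin genes Krt19 (0.71 ± 0.08) and Krt7 (0.35 ± 0.08). Of 16 neural and glial markers 1 rose and 4 fell, with Stmn2 lower by 0.70 ± 0.07 and Tubb3 by 0.58 ± 0.11. For these last 5 lists the counts were the same when adjusted over the list alone. Median, mean and camera direction differed in sign for the TCA cycle, matrix protein, Polycomb, Hox, antioxidant, endoplasmic reticulum stress, growth factor, cartilage and bone, macrophage, endothelial and epithelial lists, none of which passed camera.

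Changes were not spread evenly along the genome, which was looked at after the lists. Among genes above the median level, those on chromosome 3 had a median log2 fold change of -0.23 (95% bootstrap interval over genes -0.27 to -0.20), with 228 of 471 lower and 33 higher. Genes on chromosome 9 had a median of 0.22 (0.19 to 0.25), with 263 of 573 higher and 28 lower. Medians were also high on chromosomes 13 (0.20) and 5 (0.17) and low on chromosomes 11 (-0.13) and 6 (-0.13). For 11 of 20 chromosomes the median lay farther from that of all genes than in any of 1000 shuffles of the chromosome labels. Medians also differed between blocks within some chromosomes, though no test of a step was run. On chromosome 16, an example picked after the values were seen, the 30 expressed genes from Ppp1r2 to Sec22a had a median of 0.18. The next 30, from Pdia5 to Boc, had a median of -0.21 and the 30 from Nepro to Tbc1d23 had a median of -0.31. Removing a running median of 31 neighbouring expressed genes, an alternative chosen after seeing the data, left 3049 genes past the threshold. It ended the calls of some genes named here. The log2 fold change of Heatr1 went from 0.27 to 0.000353, that of Ttk from 0.39 to 0.11 and that of Stmn2 from -0.70 to -0.16. Idh3a went from 0.56 to 0.21, Sox9 from -0.37 to -0.18, Rfc4 from 0.43 to 0.26 and Hoxd8 from 0.51 to 0.34. Cd14 moved less, from -0.45 to -0.39. Most members named for running against their list also lost their calls, with Pmvk going from -0.37 to 0.00415, Ei24 from 0.34 to 0.07, Bcat1 from 0.26 to 0.06, Ccl25 from 0.38 to 0.14, Cdkn1b from 0.39 to 0.18, Prim1 from -0.37 to -0.20 and Odc1 from 0.32 to 0.22. Other genes stayed past the threshold with values moved by over 1.5 times. They were Cxcl12 (-0.65 to -0.40), Cxcl1 (-0.37 to -0.58), Tlr2 (-0.70 to -0.35), Ndufv1 (-0.52 to -0.29), Slc7a11 (-0.89 to -0.56), Gnl3 (0.49 to 0.32), Pfkp (0.89 to 0.58), Cth (-1.22 to -0.81) and Col12a1 (0.90 to 0.60). Only a constant per gene was removed, so the spread between replicates stayed as it was. Genes not above the median level were left unchanged. The values of Ifit1, Perp, Vldlr, Hgf, Itgb3, Lpl, Fabp4, Kdr and Tubb3 could therefore not move, nor could those of dim list members. The cytokine list missed the camera threshold with a median of -0.10 against -0.11 (adjusted p = 0.054), and 6 lists stayed past it. Removing chromosome medians, also chosen after seeing the data, ended the calls of the cytokine list (adjusted p = 0.249, median -0.09 against -0.11) and the amino acid list (adjusted p = 0.051, median -0.08 against -0.12) and left 5 lists. It also ended the calls of Ccl9 (-0.26, adjusted p = 0.0646), Ttk (0.18, 0.119), Heatr1 (0.07, 0.605), Sox9 (-0.23, 0.121), Ei24 (0.13, 0.276) and Pmvk (-0.13, 0.259). Car5b, named below, lost its call both with chromosome medians (-0.18, 0.0663) and with the running median removed (-0.18, 0.0808).

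**Figure D3:**
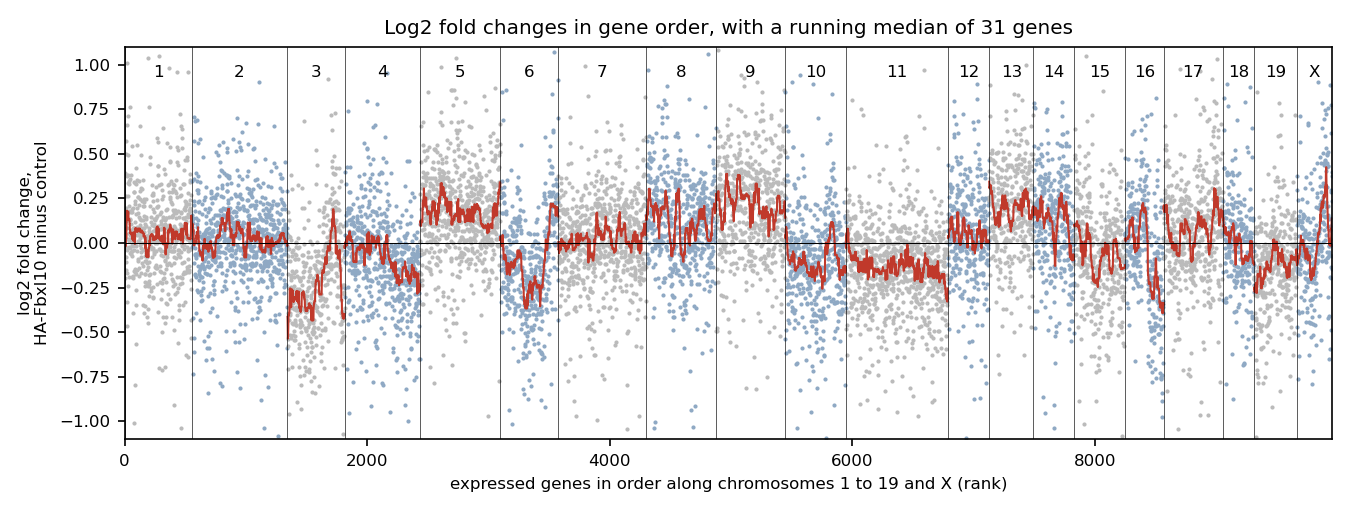
Log2 fold change of single expressed genes (vertical axis, HA-Fbxl10 minus control, points outside the axis not shown) in their order along chromosomes 1 to 19 and X (horizontal axis, rank). Grey and blue points alternate by chromosome and the red line is a running median of 31 genes, which lies below 0 along most of chromosome 3 and above 0 along chromosomes 5, 9 and 13.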

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

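The tests of probe sets outside the gene counts were planned, and what they gave is listed without an explanation. In a limma fit of all 35556 probe sets, 49 of the 1621 probe sets with several gene names were higher and 75 lower on HA-Fbxl10 arrays past an adjusted p of 0.05. They drew attention because they carry a difference between groups in probe sets left out of the report's gene counts, which only the alternative with all probe sets holds. Of the 12146 probe sets unnamed here, 226 were higher and 302 lower, drawn out for the same reason. The share past the threshold was 7.65% for probe sets with several genes and 4.35% for unnamed ones, against 14.5% for probe sets with 1 gene. The log2 fold changes of the unnamed probe sets ran from -2.41 to 1.92. Groups of 3 arrays are too small for a test of single outlying arrays.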

How the results depend on the processing

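Removal of chromosome medians or of the running median was chosen after seeing the data, and the other settings before. Every normalisation, filter, probe rule, variance model, array weighting and left-out array kept the counts of genes within 1.5 times those reported, and under these no named gene or list past the threshold reversed. An adjusted p of 0.01 left 2536 genes, 1227 higher and 1309 lower, without Hoxd8, Heatr1, Sox9, Cd14, Cxcl1, Bcat1, Kdm6a and Car5b. Camera with an estimated correlation called 0 of the 28 lists against 7, with 3 at an unadjusted p under 0.05. The estimates for the chemokine (0.00409) and cytokine (-0.00379) lists lay below the preset 0.01. A higher correlation therefore does not account for these lost calls, and this form of camera also has only 4 residual degrees of freedom. Estimates for the interferon, p53, amino acid, cholesterol and DNA replication lists were higher, 0.0222 to 0.233, and the share of each cause was not tested. Leaving out 1 array gave 3208 to 3853 genes past the threshold, with 3135 to 3548 of them shared with the full fit, and log2 fold changes of 2.29 to 2.39 for Kdm2b. Subtracting array medians raised the share of higher genes from 49.8% to 58.9%. The replicate block left 3397 genes past the threshold, of which 3348 were shared. Deviations of same-numbered arrays correlated at 0.0851, -0.283 and -0.0934, and not every array correlated best with its own number. These values gave no sign of pairing, but 3 arrays per group are too few to exclude it. Among the genes named by the rule, Heatr1, Sox9 and Cd14 lost their call under other settings fixed beforehand. Heatr1 lost it under the replicate block (adjusted p = 0.0727) and without control replicate 1 (0.0952) or 2 (0.09) or HA-Fbxl10 replicate 1 (0.0789) or 2 (0.0876). Sox9 lost it under the replicate block (0.054) and without control replicate 2 (0.0604) or HA-Fbxl10 replicate 2 (0.0588). Cd14 lost it under quantile normalisation (0.0622), the replicate block (0.0764) and without control replicate 1 (0.119) or 3 (0.085) or HA-Fbxl10 replicate 1 (0.107) or 3 (0.106). Among genes named after their values were seen, Cxcl1, Bcat1, Kdm6a and Car5b lost theirs under the replicate block and without single arrays, Cxcl1 also under quantile normalisation (0.0632), Kdm6a (0.0513) and Car5b (0.181) with array medians subtracted, and Ccl25 with averaged probe sets (0.0654). The cytokine list lost its call without the dimmest genes (0.104), with averaged probe sets (0.0515), array weights (0.0513) and the replicate block (0.0518), and the amino acid list without the dimmest genes (0.0622). Removing chromosome medians left 3455 genes and 5 lists, without the cytokine and amino acid lists, and removing the running median left 3049 genes and 6 lists, without the cytokine list, with 2529 genes shared. Under the latter Pmvk turned from -0.37 to 0.00415. Each gene counts in its own running median, and at Pmvk that median was its own change. Pmvk was thus set to the median of all expressed genes (0.00415), so its turned sign carries no meaning of its own. The table has no measure of signal over background, so what the dimmest values can show is unknown.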

Other observations

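The segment, gene-trend, array-noise and Y-linked tests below were chosen only after the results they bear on were seen, and the other tests were set before. Some genes outside the lists that changed by over 2-fold were chosen here after their values were seen, so they stand for no group. The BMP antagonist Bmper (1.54), the activin-binding Fst (1.42), Wnt5a (1.32), Fgf9 (1.80), and the vasoactive peptide genes Adm (1.84) and Edn1 (1.43) rose on the log2 scale. The cytokine gene Il7 (-1.64, and -1.05 with the running median of neighbours removed), the lipopolysaccharide-binding protein gene Lbp (-2.13), the heparin-binding growth factor gene Ptn (-1.50) and Angpt1 (-1.02), which encodes a Tie2 ligand, fell. The cadherin genes Cdh2 (1.40) and Cdh13 (1.19) and the adhesion molecule gene Mcam (1.45) rose, while the integrin and focal adhesion list as a whole did not pass camera. Ripk3, a kinase of necroptosis, fell by 2.20 and the imprinted gene Ndn fell by 2.15.

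Log2 fold changes were shifted in blocks along chromosomes. A trend with expression level or gene span is argued against as the main source of the chromosome 3 shift. The median there was -0.23 before and -0.224 after the medians of bins of both were removed. Chromosome 9 went from 0.216 to 0.195 and chromosome 5 from 0.166 to 0.143. Chromosomes 8 (0.118 to 0.0913) and 18 (0.0107 to -0.0278) moved more, so a smaller part of such a trend stays open. Blocks within chromosomes were not checked in this way. Noise between arrays is argued against too, as the largest deviation of a chromosome median on 1 array from its group mean was 0.0149. Gains or losses of chromosome segments stay open: 178 of 9376 overlapping windows of 30 neighbouring genes lay beyond the highest absolute median of 1000 shuffled orders (0.344), which shows the blocks but not their source, since a GC trend or a regional effect of Fbxl10, both untested, would give such windows too. The largest chromosome shift, 0.234 on chromosome 3, lay between the bounds set beforehand (0.1 and 0.25) for gain or loss of whole chromosomes. For chromosomes 3 and 6, blocks of 30 expressed genes argue against a change of the whole chromosome alone. Medians were -0.36 from Rps3a1 to Rit1 but 0.18 from Slc30a7 to Tifa on chromosome 3. On chromosome 6 they were -0.32 from Rtkn to Snrpg but 0.22 from Prp2 to Ldhb. A whole-chromosome change stays open for chromosomes such as 9 and 13, where all consecutive blocks had positive medians. The design does not separate a clone's karyotype from the transgene.

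Xist was lower on all 3 HA-Fbxl10 arrays. Male cells that kept a Y chromosome, in place of the labelled line, are argued against. Of 4 broadly expressed Y-linked genes chosen for this test (Eif2s3y, Kdm5d, Uty and Usp9y, of 9 measured), 0 lay above the lower quartile of all genes. Their highest value was 3.37 against a quartile of 3.69. Sry (5.43 in control and 5.56 in HA-Fbxl10 cells, limma adjusted p = 0.599) and Uba1y (4.95 and 5.24, adjusted p = 0.0815) lay above it in both groups without a difference past the threshold. Male cells without a Y chromosome would not be seen by this test and stay open. Reactivation of the whole X chromosome is argued against, since the median of expressed X-linked genes minus that of autosomal genes was -0.0112, although the 30 genes from Hnrnph2 to Alg13 had a median of 0.26, so reactivation of a part stays open. Loss of the inactive X may account for it but cannot be told apart from loss of Xist expression alone: the 8 expressed genes known to escape silencing had a median of -0.168, at percentile 3.16 of matched random lists but short of the -0.2 set beforehand, with Eif2s3x (-0.46), Utp14a (-0.44), Kdm6a (-0.30, but not past the threshold without control replicate 3 or HA-Fbxl10 replicate 1 or 3, adjusted p of 0.0565 to 0.0805) and Car5b (-0.19, but not past it without any 1 array, 0.0819 to 0.141) lower, and Mid1 (-0.14), Kdm5c (-0.08), Pbdc1 (0.06) and Ddx3x (0.12) not past the threshold. An effect of Fbxl10 on Xist was not tested.

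Of 31 chemokine genes, 9 were lower and 1 higher on HA-Fbxl10 arrays, and 21 did not pass the test. A lost copy of the Ccl gene cluster on chromosome 11 is argued against as the whole cause, because the 7 expressed chemokines outside that chromosome had a median of -0.649, against a 5th percentile of -0.208 in matched random lists, and 20 expressed genes flanking the cluster had a median of -0.05. Whether there were fewer macrophages cannot be judged from the marker levels. The marker median was 0.0200 over all 18 (0.00789 to 0.0600 without single arrays), above the bound of -0.1 set beforehand for arguing against this cause. It was 0.05 over the 11 above the lower quartile of genes (5th percentile of matched lists -0.085). However, 16 of the 18 lay below the median of all genes, many near the lower quartile, where a fall may not show. Of the brighter markers, Cd14 fell (-0.45) and Cd68 (0.11) did not pass the threshold. The chemokine list kept its camera call after the running median of neighbours was removed (adjusted p = 0.00104) but not with an estimated correlation (adjusted p = 0.317), within a range of 0.000417 to 0.317 over all its alternatives. That removal could change only the 11 expressed chemokines of the 31. A lower interferon or NF-kappaB tone in the selected cells and a direct effect of Fbxl10 stay open and were not tested.

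The 4208 genes past the threshold were compared with other splits of the 6 arrays. Of the 10 splits into 3 and 3, only the real 1 gave as many, and the highest of the others gave 0 genes in limma, with 899 at an unadjusted p under 0.05 against 6245 for the real split. With 10 splits a share under 0.05 cannot be reached. Each of the other splits also put arrays of both groups on both sides, so the difference between groups added to the spread. Their low counts therefore do not show how many genes would pass without a difference.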
